A study of Escherichia coli with 6 samples.

How the data were processed

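Genome conformation capture (GCC) libraries of Escherichia coli were analysed from 6 samples, with 2 replicates at each of 0 h, 1 h and 2 h after release from stationary phase. Per the labels' protocols, cultures in M9 minimal medium were held in stationary phase for about 2 h, diluted about 7-fold into fresh medium at 37 °C, and fixed with 1% formaldehyde for 20 min. The labels call the replicates biological but do not say whether they came from separate colonies, so that p-values measure the spread between these samples. Groups and replicate numbers were taken from the labels alone.

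The authors deposited 3 count tables per library, each holding whole-number counts per pair of restriction fragments, not normalized. From the values, the first table was taken to hold pairs whose ends each have a single placement, the second to hold pairs with an end of several possible placements, and the third to be the sum of both, which was checked pair by pair. The restriction enzyme, the aligner, its filters and the handling of PCR duplicates are not given in the sources used here. The chromosome in the deposited tables is 4639675 bp long, and coordinates are given 1-based on that sequence. The fragment tables hold 34545 fragments with a median length of 83 bp. Of 4432 gene symbols in the files, 4085 matched a current symbol in the reference gene table, 327 matched an older one and 20 had no match; that table describes a later version of the sequence and was used for names only.

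Single-placement counts per library ranged from 17758058 to 23593896, and several-placement counts from 864881 to 1202485. Counts without molecular identifiers are not independent molecules, so that binomial intervals and floors cover counting error only. The main analysis used the single-placement table. Read ends were summed in 10-kb bins, and pairs over 10 kb apart were summed between 100-kb bins and, as ends, per gene. Per-gene counts of long-distance ends carried an offset for the read-end density in the 200 kb around the gene. The origin-to-terminus ratio compared ends within 200 kb of oriC with ends within 200 kb of dif; the position of dif and the borders of the macrodomains came from background knowledge, since the files do not annotate them.

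Counts per bin, bin pair and gene were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's filter on low counts and Benjamini-Hochberg adjustment at 0.05, in a fit of all 6 libraries. The 21 contact values among 6 macrodomain regions were divided by the value expected from the regions' own long-distance ends and tested with limma 3.58.1. Single values per library were compared between 2 h and 0 h by a two-sided exact permutation test over the 90 assignments of libraries to times, whose smallest possible p is 0.022, with adjustment over a family of 9 values. An exact permutation test of 2 libraries against 2 others alone could not go below p = 0.33. Counts at an unadjusted p under 0.05 are given beside some calls. Without any change a share of about 0.05 of all tests would fall there. A count near or under that share is therefore no sign of change.

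The tested gene lists held nucleoid-associated and structural proteins, RNA polymerase and sigma factors, ribosomal proteins, rRNA, tRNA, replication and division, stationary-phase and acid resistance genes, flagella and chemotaxis, central carbon metabolism and respiration, amino acid biosynthesis, prophage genes, insertion sequences, LPS core and O-antigen, and fimbriae and curli. The fimbriae list was taken by name prefix and includes genes with no known fimbrial role. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with all other genes, while fry asks whether the list itself changed. With an estimated correlation, camera also rested on the 3 residual degrees of freedom of the fit. A call lost there therefore need not mean that the genes of a list are correlated. Values of fry are those of its directional test unless its mixed test is named. The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes genes past the threshold with the largest changes, the 3 members of each list with the smallest p at 2 h against 0 h, 7 genes in any case (dnaA, seqA, matP, mukB, hns, fis and dps), and the 3 highest and 3 lowest bins and bin pairs. Tests of read density per gene were added after the data were seen, and their examples were taken by the same list rule.

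Alternatives were library-size scaling, DESeq2 1.42.0, no filter on low counts, replicate number as a block, each library left out in turn, identical fragment pairs counted 1 time, other bin sizes and distance minimums, and other offsets. Added after seeing the data were the combined table, a terminus placed opposite oriC, and the merging of fragment pairs within 2 fragments of each other into 1 contact. On simulated counts for 2 h against 0 h, 200 features per test were changed at random places, with rises and falls balanced. Among 464 bins, the density test recovered 35.8% of changes of 1.05-fold and 91.0% of those of 1.1-fold. In the data the changed bins lay in long runs along the chromosome, so that these shares are only a guide. The contact test over 1128 bin pairs recovered 5.97% of changes of 1.2-fold, 65.7% of 1.5-fold and 100% of 2-fold. The gene test over 4143 simulated genes recovered 23.9% of changes of 1.5-fold, 62.7% of 2-fold and 86.4% of 3-fold. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for counting and plotting.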

Results

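Genome conformation capture joins DNA fragments that formaldehyde held near each other and counts the joined pairs. The density of all read ends along the chromosome follows how many copies of each region the culture held relative to other regions. E. coli cells were synchronised by a passage through stationary phase and sampled at 0 h, 1 h and 2 h after release into fresh medium, with 2 libraries per time. Single-placement counts were 19932989 and 17758058 at 0 h, 23593896 and 23144068 at 1 h, and 21386080 and 22232429 at 2 h. The comparisons asked how relative copy number along the chromosome and contacts between its regions differed as growth resumed. Replicates of each time differed by more than counting noise, so that none was counted as the same library listed again; this says nothing of how the samples were obtained.

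From 0 h to 2 h, read-end density rose around oriC, the origin of replication, and fell around the terminus, relative to the rest of the chromosome. Counts were scaled to each library's total, so that a fall here and below does not mean that copies were lost. Of the 100 10-kb bins within 500 kb of oriC, 99 rose, with a median log2 change of 0.28 (SD 0.06 over bins). Between 500 and 1000 kb from oriC, 81 of 100 bins rose, and their median was 0.10. Between 1500 and 2000 kb from oriC, 97 of 100 bins fell, with a median of -0.14, and all 64 bins farther away fell, with a median of -0.22. Over the chromosome, 182 of 464 bins were higher and 180 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With identical fragment pairs counted 1 time, 122 were higher and 95 lower. With scaling by library size alone the split was 150 higher and 210 lower, and the median of all bins moved from -0.01 to -0.05.

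**Figure D1:**
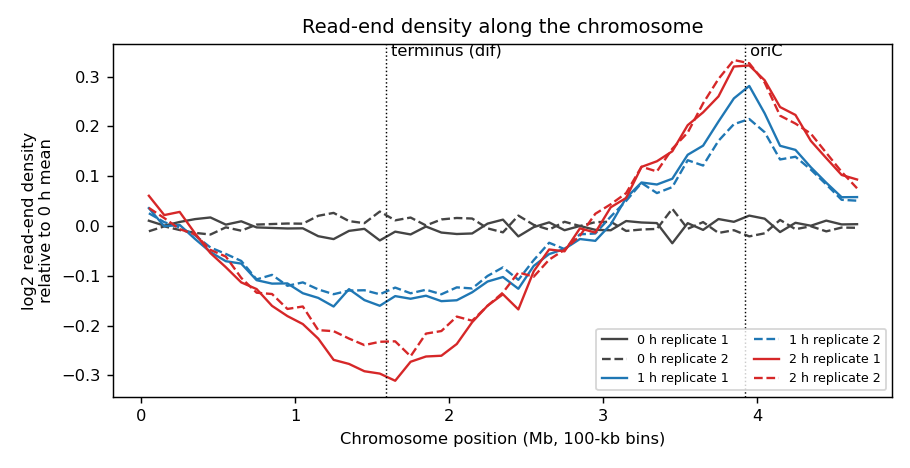
Log2 read-end density in 100-kb bins relative to the mean of the 0 h libraries (vertical axis) against chromosome position in Mb (horizontal axis), with 1 line per library; colours mark times and line styles mark replicates. Both 2 h libraries lie above both 0 h libraries around oriC and below them around the terminus, and the 1 h libraries lie between.

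The 10-kb bin with the highest change ran from 3820001 to 3830000 and holds spoT, which makes and degrades the alarmone ppGpp, rpoZ, the omega subunit of RNA polymerase, and recG, a helicase that acts on branched DNA. It rose by 0.40 ± 0.03 (log2, SE, n = 2 per time; edgeR adjusted p = 9.56e-07). The bin from 3840001 to 3850000, with the ilvB and ilvN genes of branched-chain amino acid synthesis and the uhp genes of hexose phosphate uptake, rose by 0.39 ± 0.03. The bin from 3900001 to 3910000, with the pst genes of phosphate transport, phoU and the bgl genes of beta-glucoside use, also rose by 0.39 ± 0.03. The lowest bin ran from 1210001 to 1220000, with icdC and iraM, an anti-adaptor that protects the stress sigma factor RpoS, at -0.32 ± 0.09. The bin from 1390001 to 1400000 followed, with fnr, the regulator of anaerobic growth, at -0.26 ± 0.06, and that from 1540001 to 1550000, with the fdn genes of formate dehydrogenase, at -0.26 ± 0.04. The bin from 1210001 ranged from -0.45 to -0.17 with a library left out. It did not pass without 0 h replicate 2 (-0.17, edgeR adjusted p = 0.11), where it was no longer the lowest, or without 2 h replicate 1 (-0.20, edgeR adjusted p = 0.070).

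The log2 origin-to-terminus ratio was 0.35 ± 0.04 at 0 h, 0.71 ± 0.05 at 1 h and 0.92 ± 0.03 at 2 h (SD, n = 2). The difference of 0.57 between 2 h and 0 h, a 1.49-fold change, had an exact permutation p of 0.022, the smallest these libraries can give, and 0.20 after adjustment over the 9 single values. Both 2 h libraries lay above both 1 h libraries, which lay above both 0 h libraries.

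**Figure D2:**
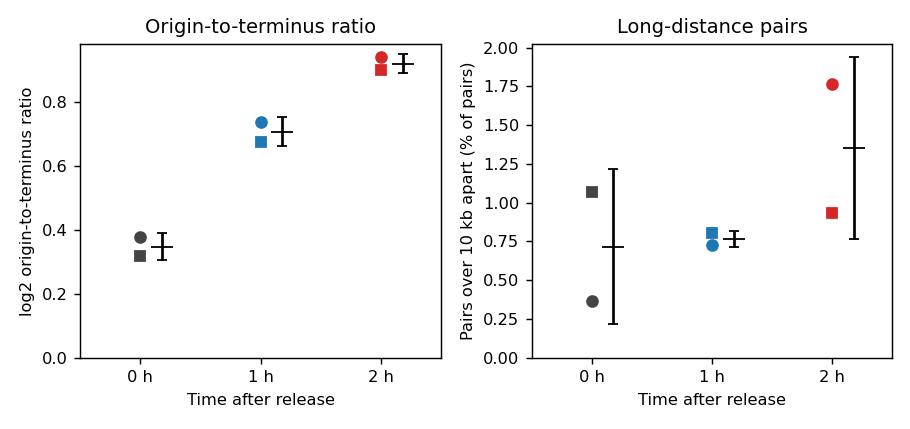
Left, the log2 origin-to-terminus ratio; right, the percent of pairs over 10 kb apart, each against time after release in hours. Circles are replicate 1, squares replicate 2, and bars give the mean and SD. The ratio separates the times, while the 0 h and 2 h libraries overlap in the share of long-distance pairs.

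Read density per gene at 2 h against 0 h was tested after the data were seen, and 827 of 4449 genes were higher and 610 lower by edgeR with Benjamini-Hochberg adjustment. This measure has no offset for position, so that a gene's value also follows its distance from oriC. The rRNA operons rrnC, rrnA, rrnB and rrnE, for example, lie 18.6, 112, 244 and 285 kb from oriC. Position was not separated from gene function in the list counts that follow. Some members of the lists of rRNA and RNA polymerase genes rose and none fell, and some members of the flagella and prophage lists fell and none rose. Of 12 measured rRNA genes, 4 rose and 0 fell, with a median of 0.29, and 4 rose when adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.11, and 0.86 with an estimated correlation). Of 19 genes of RNA polymerase and its sigma factors 9 rose and 0 fell, 9 when adjusted over the list alone, among them rho, the transcription terminator (0.37 ± 0.06), rpoB, the beta subunit (0.26 ± 0.05), and rpoH, the heat-shock sigma factor (0.25 ± 0.06). Of 53 flagella and chemotaxis genes, 12 fell and 0 rose, 8 when adjusted over the list alone, with a median of -0.16; tap, a chemoreceptor, changed by -0.26 ± 0.06, fliG, a motor protein, by -0.20 ± 0.05, and trg, another chemoreceptor, by -0.25 ± 0.06. Of 238 prophage genes, 39 fell and 0 rose, 25 when adjusted over the list alone, with a median of -0.15, among them stfR of the Rac prophage (-0.25 ± 0.05) and nohQ of Qin (-0.41 ± 0.09). Camera placed flagella (adjusted p = 2.1e-06) and prophage genes (adjusted p = 3.1e-06) lower and RNA polymerase genes (adjusted p = 0.012) and amino acid genes (adjusted p = 0.046) higher; with an estimated correlation the adjusted p were 0.16, 0.68, 0.68 and 0.86, so that none of these calls held. For flagella the estimated correlation was -0.0030, under the preset 0.01, so that this loss cannot be put down to correlation between its genes. By fry's directional test 0 of 14 lists passed, with a smallest adjusted p of 0.055. Its mixed test, which allows members to change in either direction, passed every list but ribosomal proteins (fry mixed adjusted p = 0.075). In the other comparisons the balance differed: 209 of 4449 genes were higher and 1 lower at 1 h against 0 h by edgeR, and 0 passed at 2 h against 1 h, with 376 at an unadjusted p under 0.05. Camera passed 5 and 3 lists there, and with an estimated correlation 0 lists (smallest adjusted p = 0.27 and 0.16).

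Other lists went both ways on this measure without an offset for position. Of 90 amino acid biosynthesis genes, 25 rose and 10 fell (27 and 11 when adjusted over the list alone), with ilvA, ilvD and metE among those that rose (0.38 ± 0.06, 0.36 ± 0.06 and 0.36 ± 0.06). Of 69 genes of central carbon metabolism and respiration 17 rose, including atpA and atpD of ATP synthase (0.39 ± 0.06 and 0.36 ± 0.06), and 12 fell; adjusted over the list alone, 17 rose and 13 fell. Of 47 replication and division genes, 14 rose and 3 fell by either adjustment, including adjusted over the list alone. Of 39 stationary-phase and acid resistance genes 2 rose and 9 fell, the same counts as when adjusted over the list alone; katE, a catalase, changed by -0.23 ± 0.05, osmC, a peroxidase, by -0.27 ± 0.07, and aldB, an aldehyde dehydrogenase, by 0.27 ± 0.05. Of 54 ribosomal protein genes, 4 rose and 4 fell, 0 in either direction when adjusted over the list alone, with a median of 0.11. Of 29 genes of nucleoid-associated and structural proteins, 5 rose, including gyrB of DNA gyrase (0.38 ± 0.05), and 5 fell, including topA, topoisomerase I (-0.22 ± 0.05), by either adjustment, including adjusted over the list alone. Of 45 LPS core and O-antigen genes 9 rose and 6 fell, also when adjusted over the list alone; of 80 tRNA genes 7 rose and 1 fell (2 and 0 adjusted over the list alone); of 92 genes in the fimbriae list 5 rose and 7 fell, and of 59 insertion sequence genes 1 rose and 5 fell, with 0 calls in both lists when adjusted over the list alone.

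Among the genes named in any case, dnaA, the replication initiator, 42.8 kb from oriC, rose in read density by 0.41 ± 0.05 (edgeR adjusted p = 0.0029). The values of seqA, which sequesters new origins, mukB, of the chromosome condensin, and hns, a nucleoid protein that silences genes, were -0.17, -0.14 and -0.17 and did not pass (edgeR adjusted p = 0.080, 0.073 and 0.085). Those of matP, which binds the terminus region, dps, which compacts DNA in stationary phase, and fis, a nucleoid protein of early growth, were -0.12, -0.10 and 0.08. Relative to the read density of the 200 kb around each gene, 0 of 4449 genes passed in 2 h against 0 h by edgeR, with 71 at an unadjusted p under 0.05, and 0 by DESeq2. On this relative measure camera passed 6 of 14 lists at 2 h against 0 h, with flagella higher (median 0.06) and ribosomal proteins (median -0.04, adjusted p = 2.2e-08), O-antigen, prophage, stationary-phase and tRNA genes lower. With an estimated correlation 0 lists passed in any comparison (smallest adjusted p = 0.82), and 0 by fry. The medians of O-antigen (0.0059) and prophage genes (0.0094) were nevertheless above 0. Camera passed 4 at 1 h against 0 h and 0 at 2 h against 1 h.

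The change was already present at 1 h. Against 0 h, 147 of 464 bins were higher and 123 lower by edgeR with Benjamini-Hochberg adjustment, including 96 of the 100 bins within 500 kb of oriC (median 0.19), and 52 of the 64 bins over 2000 kb away were lower (median -0.10). With scaling by library size alone the split was 126 higher and 189 lower. The lower calls depended most on the libraries and the counting. Without 1 h replicate 1, 111 bins were higher and 22 lower, without 1 h replicate 2, 122 and 38, and without 0 h replicate 2, 139 and 75. With identical fragment pairs counted 1 time, 43 were higher and 10 lower. From 1 h to 2 h, 30 bins were higher, 29 of them within 500 kb of oriC, and 56 were lower, 42 of them over 2000 kb from oriC. DESeq2 placed 66 bins higher and 66 lower. This count moved with the library left out: no bin passed without 2 h replicate 1 (126 at an unadjusted p under 0.05), 4 passed without 1 h replicate 2 and 13 without 1 h replicate 1, while 80 passed without 2 h replicate 2, 138 without 0 h replicate 1 and 144 without 0 h replicate 2.

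Contacts over 10 kb apart rose mostly on the side of oriC and fell mostly on the side of the terminus. At 2 h against 0 h, 74 of 1128 pairs of 100-kb bins were higher and 52 lower by edgeR with Benjamini-Hochberg adjustment. Of the 74, 63 had both bins on the side of the chromosome nearer oriC, and of the 52, 50 had both bins on the side nearer the terminus. By separation, 10 pairs were higher and 8 lower among 94 pairs of same or adjacent bins, 49 and 37 among 423 pairs at 200 kb to 1 Mb, and 15 and 7 among 611 pairs farther apart. DESeq2 called 13. Leaving out 2 h replicate 2 left 8 bin pairs and leaving out 2 h replicate 1 left 17; 60 passed without 1 h replicate 1, 64 without 0 h replicate 2 and 76 without 1 h replicate 2.

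The highest of these pairs joined the bins from 3700001 and 4600001 (0.95 ± 0.24, log2, SE; edgeR adjusted p = 0.0054), the bin from 4400001 with itself (0.91 ± 0.29) and the bins from 3700001 and 4000001 on either side of oriC (0.90 ± 0.15). The lowest joined the bins from 1400001 and 1500001 (-0.93 ± 0.23), from 1600001 and 2000001 (-0.90 ± 0.21) and from 1200001 and 1500001 (-0.89 ± 0.23), all in the terminus region. The value of the bin from 4400001 with itself was -0.30 when pairs over 1 kb apart were counted. Of these 6 pairs, all but that of the bins from 3700001 and 4000001 lost their call without 2 h replicate 2. The bin from 4400001 with itself also lost it without either 0 h library, 1 h replicate 1 or 2 h replicate 1. The bins from 3700001 and 4600001 lost it without 0 h replicate 1 and were at 1.55 without 0 h replicate 2. The bins from 1400001 and 1500001 lost it without 2 h replicate 1. The bins from 1200001 and 1500001 lost it without 2 h replicate 1 and without 0 h replicate 2, where they were at -0.58. Across bin pairs, which are not independent replicates, the contact change followed the summed density change of the 2 bins with a slope of 0.98 and Pearson's r of 0.81; 73 of the 74 higher pairs and all 52 lower pairs had the sign of their density change. With the bins' read-end densities as an offset, edgeR called 0 bin pairs in each comparison, with 54 at an unadjusted p under 0.05 in 2 h against 0 h.

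**Figure D3:**
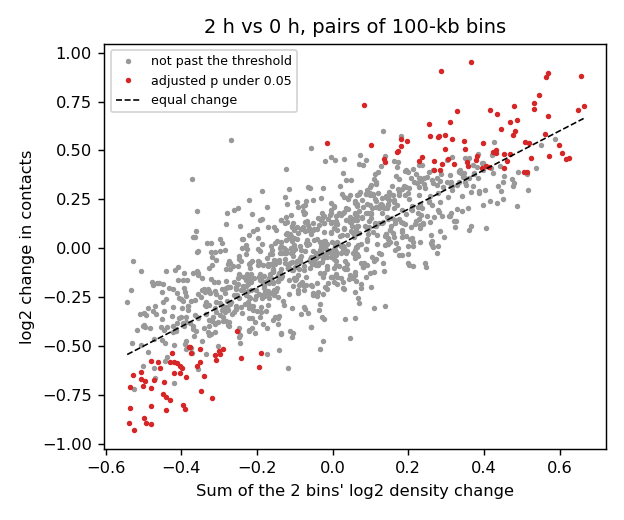
Log2 change in contacts between pairs of 100-kb bins from 0 h to 2 h (vertical axis) against the sum of the 2 bins' log2 changes in read-end density (horizontal axis); each point is 1 of 1128 bin pairs, red where the adjusted p was under 0.05, and the dashed line marks equal change. The points follow the line with a slope of 0.98.

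At 1 h against 0 h, 7 bin pairs were higher and 0 lower by edgeR, 6 of them at 200 kb to 1 Mb; DESeq2 called 0, with 80 at an unadjusted p under 0.05. Without either 1 h library 0 passed, without either 2 h library 1 passed, and 13 and 19 passed without 0 h replicate 1 and 2. At 2 h against 1 h, 0 bin pairs passed by edgeR, with 87 at an unadjusted p under 0.05, and 0 by DESeq2.

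Pairs over 10 kb apart made up 0.365% and 1.07% of pairs at 0 h, 0.727% and 0.802% at 1 h, and 1.77% and 0.936% at 2 h. The means of 0.718% ± 0.498 at 0 h and 1.35% ± 0.587 at 2 h (SD, n = 2) differed by less than the replicates could resolve (exact permutation p = 0.22). With identical fragment pairs counted 1 time, which removes counts at short separations above all, the shares were 42.2% and 65.2% at 0 h, 62.1% and 63.8% at 1 h, and 77.2% and 67.6% at 2 h. The difference between 2 h and 0 h was then 18.7 percentage points (exact permutation p = 0.089). The size of these shares therefore depended on how identical pairs were counted. Pairs under 1 kb apart made up 99.2% ± 0.507 at 0 h and 98.6% ± 0.589 at 2 h (exact permutation p = 0.22, adjusted 0.33). The shares at 1 to 10 kb (0.0926% and 0.0923%), 10 to 100 kb (0.0282% and 0.0547%), 100 kb to 1 Mb (0.282% and 0.535%) and over 1 Mb (0.407% and 0.761%) also overlapped between 0 h and 2 h. From 10 kb to 1 Mb the contact density hardly depended on separation, with log-log slopes from -0.03 to 0.00. Over 10 to 100 kb alone the slopes were -0.16 ± 0.04 and 0.03 ± 0.03 at 0 h, -0.01 ± 0.03 and -0.10 ± 0.03 at 1 h, and -0.01 ± 0.02 and -0.02 ± 0.02 at 2 h (bootstrap SE). The bootstrap treats fragment pairs as independent, although 57.8% to 65.2% of those over 10 kb apart had a neighbour in their own library. These errors are therefore likely too small, and replicates of the same time differ. Whether the lines of 0 h replicate 1 and 1 h replicate 2 departed from level there is thus not settled.

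**Figure D4:**
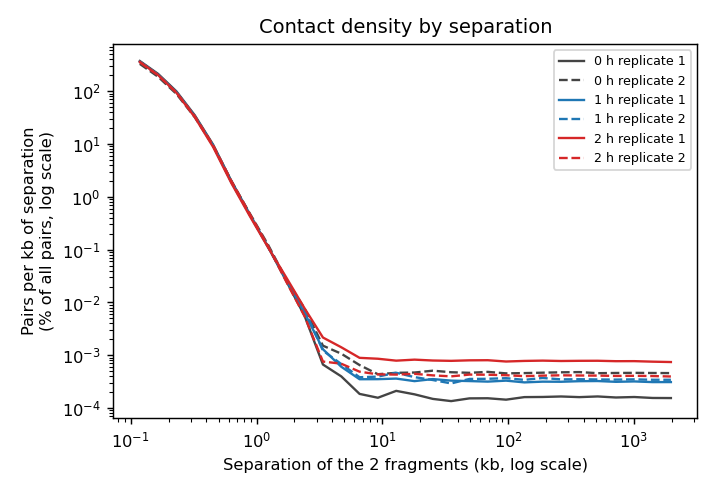
Pairs per kb of separation as a percent of all pairs (vertical axis, log scale) against the separation of the 2 fragments in kb (horizontal axis, log scale), with 1 line per library. All 6 lines drop steeply over short separations and change little from 10 kb to 1 Mb (slopes from -0.03 to 0.00), at heights that differ between libraries.

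Macrodomains are large regions whose loci contact each other more than the rest of the chromosome. After division by the value expected from the regions' ends, the log2 contacts of a region with itself lay near 0 in every library. They ran from -0.11 (NS-right, 2 h replicate 2) to 0.03 (Ter, 0 h replicate 1). The expected value makes no allowance for the pairs within 10 kb that were left out, which lowers these values. No large excess of contacts within regions was thus seen at any time, but a small one cannot be excluded. Of the 21 divided contact values, 0 passed in any of the 3 comparisons by limma. For 1 h against 0 h, 2 h against 1 h and 2 h against 0 h, 0, 2 and 2 had an unadjusted p under 0.05. The Right macrodomain with itself had the smallest p at 2 h against 0 h, with a log2 change of -0.05 ± 0.02 (limma adjusted p = 0.46); counting pairs over 100 kb apart it was -0.09 ± 0.03 and passed (limma adjusted p = 0.044). Contacts among the 10-kb flanks of the 7 rRNA operons had log2 observed over expected values of -0.08 ± 0.19 at 0 h, -0.11 ± 0.12 at 1 h and 0.20 ± 0.03 at 2 h (SD, n = 2; exact permutation p = 0.18 for 2 h against 0 h, adjusted 0.33). That difference of 0.27 was 0.50 for pairs over 1 kb apart and 0.36 for pairs over 100 kb apart, each with an exact permutation p of 0.044. For pairs over 1 kb the expected value also counts ends of pairs 1 to 10 kb apart, which cannot join different operons. The means were then -0.56 at 0 h and -0.07 at 2 h. The 0.50 thus also depends on each library's share of long-distance pairs and is no stronger sign of contacts between operons. For pairs over 100 kb the expected value still counts rrnB with rrnE, whose flanks lie less than 100 kb apart and cannot be seen joined. The p-values were not adjusted over these settings. The rRNA flank difference was 0.03 with 25-kb flanks (exact permutation p = 0.78) and 0.17 with neighbouring fragment pairs merged (exact permutation p = 0.29). Counts with several placements made up 4.68% ± 0.056 at 0 h, 4.83% ± 0.027 at 1 h and 4.69% ± 0.036 at 2 h (SD, n = 2; exact permutation p = 0.96).

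Long-distance ends per gene, relative to local copy number, changed for 1 gene. At 1 h against 0 h ygjR, a predicted oxidoreductase at 3235333 to 3236319, fell by 1.52 on the log2 scale (SE 0.31; edgeR adjusted p = 0.029), from 37 and 74 ends at 0 h to 22 and 34 at 1 h. It did not pass by DESeq2 (adjusted p = 0.33), and by edgeR it did not with neighbouring fragment pairs merged (adjusted p = 0.31), with no offset (adjusted p = 0.066) or for pairs over 1 kb apart (adjusted p = 0.92). Nor did it pass without 0 h replicate 1, 0 h replicate 2 or 1 h replicate 1 by edgeR (adjusted p = 0.13, 0.094 and 0.39). At 2 h against 0 h, 0 of 4221 genes passed by edgeR, with 181 at an unadjusted p under 0.05, and 0 by DESeq2. At 2 h against 1 h, 0 passed by edgeR, with 159 at an unadjusted p under 0.05, and 0 by DESeq2.

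The members with the smallest p in each list at 2 h against 0 h are given as log2 values with SE, and none passed (smallest edgeR adjusted p = 0.92). For flagella the values were 1.14 ± 0.34 for flgG, a rod protein, 0.46 ± 0.19 for fliD, the filament cap, and 0.35 ± 0.19 for fliG. For stationary-phase genes they were 0.72 ± 0.21 for csiD, -0.66 ± 0.25 for ygaM and -0.89 ± 0.42 for gadB, a glutamate decarboxylase of acid resistance; 1 of the 37 measured members was higher when adjusted over the list alone. For RNA polymerase and sigma factors they were 0.69 ± 0.25 for greA, a transcript cleavage factor, -0.47 ± 0.21 for rpoD, the main sigma factor, and 0.64 ± 0.43 for dksA, a partner of ppGpp. For amino acid genes they were 0.72 ± 0.25 for hisG, -0.40 ± 0.17 for thrA and -0.37 ± 0.19 for leuA. For central carbon genes they were 0.53 ± 0.25 for aceE of pyruvate dehydrogenase, 0.37 ± 0.20 for gpmM, a phosphoglycerate mutase, and 0.30 ± 0.16 for nuoG of respiratory complex I. For replication and division they were -0.36 ± 0.16 for xerC, a recombinase, 0.49 ± 0.27 for ftsL, a division protein, and -0.31 ± 0.17 for dnaA. For nucleoid proteins they were -0.68 ± 0.36 for dps, 0.28 ± 0.16 for gyrB and 0.27 ± 0.17 for topB, topoisomerase III.

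For ribosomal proteins the values were -0.54 ± 0.34 for rpsD, -0.81 ± 0.52 for rplN and 0.52 ± 0.34 for rplI. For O-antigen genes they were -1.44 ± 0.55 for rfbX, -2.02 ± 0.78 for rfbC and -0.66 ± 0.31 for rfbB. For the fimbriae list they were -0.67 ± 0.26 for ybgQ, -1.88 ± 0.78 for yfcO and 0.78 ± 0.34 for yfcZ. For prophage genes they were -1.63 ± 0.59 for both rnlA, a toxin, and its neighbour yfjM, which had the same counts in every library, and -1.20 ± 0.46 for yfjO. For tRNA they were -1.23 ± 0.56 for serX, 1.14 ± 0.61 for alaX and 0.69 ± 0.38 for proK. The tRNA gene alaX had 0 ends in 0 h replicate 1, was at 0.58 without that library and reached 7.31 with another library left out. For insertion sequences they were 0.91 ± 0.41 for insP, -1.44 ± 0.73 for insI copy 2 and -1.14 ± 0.73 for insI copy 3. For rRNA they were -0.93 ± 0.74 for rrsC, -0.66 ± 0.53 for rrfB and -0.52 ± 0.66 for rrfA. The insI and rRNA genes have near-identical copies, so that their values are uncertain. The other genes named in any case had values of -0.10 ± 0.38 for seqA, 0.38 ± 0.31 for matP, -0.00 ± 0.11 for mukB, 0.09 ± 0.37 for hns and -0.12 ± 0.37 for fis. With a library left out, 27 of the 47 named genes moved by over 1.5 times at 2 h against 0 h, and 6 of the 27 turned sign.

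As groups, ribosomal protein genes had fewer long-distance ends than other genes at 1 h against 0 h (median -0.30, 13 of 51 members above 0; camera adjusted p = 0.0031), with 0 members past the test over all genes and 0 when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.71), fry gave an adjusted p of 0.61, and without 0 h replicate 2 or 1 h replicate 1 camera gave an adjusted p of 0.71 or 0.35. In 2 h against 0 h and in 2 h against 1 h, 0 of 14 lists passed by camera, with smallest adjusted p of 0.50 and 0.057, and 0 by fry.

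The files also list pairs of the chromosome with 3 other sequences, named for lambda, pUC19 and pRS426. Single-placement pairs with the lambda sequence numbered 3 and 2 at 0 h, 26 and 0 at 1 h, and 23 and 2 at 2 h, and those with pUC19 numbered 3 and 2, 4 and 1, and 7 and 2. With the pRS426 sequence 0 single-placement pairs were listed in each of the 6 libraries. A count of 0 was taken to allow up to 3 counts, which were 0.127 to 0.169 ppm of a library's counts and 0.130 ppm in 1 h replicate 2, the library with 0 lambda pairs. Among counts with several placements the pRS426 sequence had 9 and 2 pairs at 0 h, 0 and 0 at 1 h, and 9 and 2 at 2 h. The 26 lambda pairs had an exact 95% binomial interval of 0.720 to 1.61 ppm of that library's counts. What these sequences stand for, what amount of each was added and at which step is not given in the sources used here.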

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

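The search for signal in counts that the comparisons do not use was made after the data were seen. Pairs of the chromosome with pUC19, a cloning vector that carries part of lacZ, were listed among counts with several placements in every library, above the 3 counts that a count of 0 allows. They numbered 2626 and 2054 at 0 h, 2902 and 3054 at 1 h, and 2576 and 2785 at 2 h. Of the 15997 such pairs, 92.1% had their chromosomal end at fragments of lacZ or lacI. Single-placement pairs with pUC19 numbered only 1 to 7 per library. As pUC19 shares lac sequence with the chromosome, the pairs with several placements cannot be read as joins of the chromosome with the vector. In the same table the pRS426 sequence had 9 pairs with the chromosome in 0 h replicate 1 and 9 in 2 h replicate 1. Among single-placement counts, the lambda sequence lay above 3 counts in 1 h replicate 1 (26) and 2 h replicate 1 (23), and pUC19 in the same libraries (4 and 7).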

How the results depend on the processing

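Merging of neighbouring fragment pairs, left-out libraries for gene lists and tests of read density per gene were chosen after the data were seen. Main results were compared under settings other than leaving out a library. A count of calls was taken as kept if its total was equal or within 1.5-fold, whatever its split into higher and lower. A single value was kept if its sign and the side of an unadjusted exact permutation p of 0.05 stayed. By these rules 93 were kept, 29 moved, 2 came to pass and 2 reversed. The origin-to-terminus difference was kept under each of these settings, although its exact permutation p after adjustment was 0.20. It ranged from 0.54 to 0.60 with a library left out, where without either 1 h library the exact permutation test cannot go below p = 0.067. The cause of the changes was not tested unless named.

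With 50-kb bins, of which there are fewer, 76, 53 and 81 density bins passed (1 h against 0 h, 2 h against 1 h, 2 h against 0 h); with identical fragment pairs counted 1 time, 53, 30 and 217; by DESeq2, 132 at 2 h against 1 h. Of contacts at 1 h against 0 h, 62 passed with 200-kb bins, 11 with identical pairs counted 1 time, 1 over 1 kb, 0 by DESeq2 and 0 with the density offset; at 2 h against 1 h, 18 with 200-kb bins and 1 with merging; at 2 h against 0 h, 13 by DESeq2 and 0 with the offset. Of genes at 1 h against 0 h, 0 passed with merging, DESeq2, no offset or pairs over 1 kb, and 2 at 2 h against 0 h with no offset. For macrodomains 1 passed at 2 h against 0 h over 100 kb. Of lists, 2 passed with merging at 1 h against 0 h, 0 with an estimated correlation, and 1 with merging at 2 h against 1 h. The rRNA flank difference was 0.50 over 1 kb, where it also depends on the long-distance share. It was 0.36 over 100 kb, where the expected value also counts operons too close to be seen joined. With merging it was 0.17 and with 25-kb flanks 0.03.

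The 1 to 10 kb share difference was 0.0531 with identical pairs counted 1 time, and the slope difference over 10 to 100 kb was 0.0449. Of values that had not passed, signs turned with no offset for dnaA (0.0165), hns (-0.15) and fis (0.0200), with merging for seqA (0.14), and for mukB with identical pairs counted 1 time (0.00492), pairs over 1 kb (0.0082) or 100 kb (0.0166) and a 50-kb offset (0.0131). The bin from 4400001 with itself was -0.30 over 1 kb.

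With a library left out, counts ranged from 133 to 296, 0 to 144 and 326 to 351 density bins, and from 0 to 19, 0 to 5 and 8 to 89 bin pairs; genes from 0 to 2 at 1 h against 0 h; lists from 0 to 2, 0 to 1 and 0 to 1; and density per gene relative to its neighbourhood from 0 to 11 at 1 h against 0 h and 0 to 1 at 2 h against 0 h. The differences ranged from 0.14 to 0.41 for rRNA flanks, 0.218 to 1.048 for the share over 10 kb, 0.00991 to 0.0432 for 10 to 100 kb, 0.0875 to 0.419 for 100 kb to 1 Mb, 0.121 to 0.586 over 1 Mb, -1.0498 to -0.216 under 1 kb, -0.00647 to 0.00575 for 1 to 10 kb, -0.0316 to 0.0475 for several placements and -0.0146 to 0.00835 for the slope. Values ranged from -0.41 to 0.18 for fis, -0.00105 to 0.21 for hns, -2.21 to 0.21 for insI copy 3, -0.0946 to 0.12 for mukB, -0.95 to 0.57 for rpsD and -0.19 to 0.0831 for seqA. With the sign kept, 21 more moved by over 1.5 times, alaX among them: dps (-0.83 to -0.37), fliG (0.19 to 0.49), gadB (-1.22 to -0.0565), gpmM (0.26 to 0.60), hisG (0.49 to 1.26), leuA (-0.47 to -0.22), matP (0.15 to 0.89), nuoG (0.0796 to 0.73), proK (0.47 to 1.27), rfbC (-2.91 to -1.06), rfbX (-2.18 to -0.69), rnlA and yfjM (-2.30 to -0.98), rplI (0.30 to 1.07), rpoD (-0.71 to -0.28), rrfA (-0.61 to -0.33), rrfB (-1.77 to -0.18), topB (0.11 to 0.55), yfcZ (0.46 to 1.64) and yfjO (-1.93 to -0.43).

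With replicate number as a block, 132 density bins passed at 2 h against 1 h, 0 and 40 bin pairs at 1 h and 2 h against 0 h, 0 genes at 1 h against 0 h (ygjR at an edgeR adjusted p of 0.12), and mukB was 0.00183. The labels state no shared batch; replicate differences of 2 times correlated at 0.13 to 0.25 across density bins, where numbers carry some shared signal, and at -0.02 to 0.01 across bin pairs and genes. With 2 numbers per time this does not settle a pairing.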

Other observations

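Of the tests below, those of the shared fold and similar sequences were chosen only after the result was seen; the others were written down beforehand. Some distant fragment pairs recurred: 157 fragment pairs over 10 kb apart, in 81 groups of neighbours, were counted in all 6 libraries. The most frequent joined yeiQ with xerC (173 counts over the 6 libraries), tsx, a nucleoside channel, with glnL, a nitrogen sensor kinase (170), paaK with tdcE (142) and xapA with aaeA (111). A further pair joined icd, the isocitrate dehydrogenase gene in which the e14 prophage sits, with icdC at the far end of e14 (50). Gene names here only locate the fragments, and some recurrent ends were far shorter than the median of 83 bp. The fragment in glnL, from 4053522 to 4053537, also recurred with rhaT (105) and with hofN and hofO (24). The end in hyfB ran from 2600538 to 2600539 and that in lplA from 4621931 to 4621935.

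From 10 kb to 1 Mb the slope of contact density was between -0.03 and 0.00 in every library, although over 10 to 100 kb it was -0.16 in 0 h replicate 1 and -0.10 in 1 h replicate 2. Too few pairs to see a decay is argued against by the largest bootstrap standard error of the slope, 0.0108. That error is likely too small, as it treats fragment pairs as independent, but the slopes of the libraries themselves spread only from -0.03 to 0.00. A fold shared by the libraries would make bin pairs depart together from the product of their ends and stays open: the mean correlation across bin pairs was 0.053 (95% bootstrap interval 0.0300 to 0.0826), which is small but above 0. The fragment pairs counted in all 6 libraries were not left out, and they raise the same bin pairs in each library. The bootstrap also treats bin pairs that share a bin as independent. A value above 0 is therefore no evidence of a fold by itself. Random joining of ends in the tube remains open too: it needs long-distance ends to follow copy number, and their change in the origin-to-terminus ratio differed from that of all ends by 0.0172 (log2). Contacts formed inside cells would follow copy number too, so that random joining may account for the level, as a hypothesis, but this test does not separate it from an evenly mixed chromosome.

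The share of pairs over 10 kb apart differed 2.93-fold between the 0 h replicates, and 1.54-fold with identical fragment pairs counted 1 time, where the ratio of pairs over 10 kb to all shorter pairs differed 2.57-fold. Their total counts differed 1.12-fold, and sequencing depth was not tested as a cause. Counting several fragment pairs per joined molecule is argued against, because the fold was 3.22 after neighbouring pairs were merged into 1 contact. No biological explanation was tested, as both libraries belong to the same time. The labels give no batch with which to test the preparation of the libraries, and duplicates were not tested as a cause.

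For the recurrent fragment pairs, chance is argued against, as random joins in proportion to the fragments' ends would give 1.58e-10 such pairs. The share of counts on these pairs spread over 1.48-fold between libraries and the long-distance share over 4.83-fold, but pairs chosen for their presence in all libraries are bound to spread less, so that joins made during proximity ligation stay open. Similar sequences stay open too: 16.6% of the recurrent pairs were also listed among pairs with several placements, against 0.314% of pairs seen in a single library. That test replaced an earlier one with a different measure, whether a fragment occurred in any pair with several placements, which was saturated because 97.3% of fragments did. The assignment of reads to very short fragments was not tested as a cause. No biological explanation was tested, as the pairs recur at all times.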
